A study of Homo sapiens with 12 samples.

How the data were processed

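The series held 12 RNA sequencing samples of MDA-LM2 cells, 2 per group. Per the labels, cells were seeded 48 hours before lipofection with 100 pmol of RNA per well, and total RNA was taken 48 hours after it; mock wells received no RNA. Libraries came from a stranded total RNA kit for small inputs. Alignment with STAR 2.7 to hg38 was stated in the submitters' processing notes. The deposited summaries have the layout of MISO, a tool that estimates isoform shares from reads; its version was not given in the sources used here. The authors' summaries give, for each skipped-exon event, the inclusion level as a fraction from 0 to 1 with a posterior interval and the number of reads in each class: explained by the inclusion isoform only, by the skipping isoform only, by both or by neither. The authors' comparison tables give the difference of each RNA from mock and a Bayes factor, a score of the evidence for a difference, with a cap of 1e12. Each condition had 1 summary, to which the labels of both of its samples point. The interval was taken to be the 95% interval that MISO gives by default.

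The files held 47845 events on 40479 cassette exons. Their coordinates were checked against the hg38 sequence and GENCODE 44: 99.5% of exons had AG before and GT or GC after them, and 96.1% matched an annotated exon at both ends. Where an exon had several events, the one with the most reads was used. The exons with at least 20 test reads (inclusion only plus skipping only) numbered 19982 in mock, 19684 in WT, 15079 in structured, 18720 in loopN, 20401 in unstructured and 20708 in loopN_unstructured. Their median number of test reads lay between 68 in structured and 110 in unstructured. Reads that fit neither isoform were 59.7% to 66.6% of the reads assigned to events and were left out.

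The main comparison was a two-sided Fisher's exact test on the inclusion-only and skipping-only reads of 2 pooled libraries, for exons with at least 20 such reads in each. An exon was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the exons tested, with deposited inclusion levels at least 0.1 apart. Direction was taken from the deposited levels. The rule did not require the tested reads to go the same way or to lie as far apart. The second was the authors' Bayes factor of at least 10 with the same difference. Comparisons were each RNA with mock and 5 pairs of RNAs. An exon set 1 library apart when it differed from each of the other 5 in the same direction by at least 0.1 with unadjusted p under 0.05 in all 5 tests. Correlations across exons were computed for pairs of differences, with simulated binomial reads beside those that share mock. The level of a gene was the number of reads compatible with its largest event, scaled to reads per 1000000 such reads in the library, on the log2 scale with a pseudocount of 1, for genes with a mean of at least 5 after scaling. Lists were set beside 10000 random lists of the same size and of like read number or level.

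These tests, thresholds, alternatives, naming rules and 11 gene lists were chosen before the data were examined. The lists were PLEC with ERRFI1, the U2 snRNP and branch point, SR proteins and kinases, hnRNPs and splicing regulators, genes with splicing tied to the epithelial-mesenchymal transition, cytoskeleton and adhesion, interferon and RNA sensing, apoptosis, cell cycle and DNA damage, and markers of epithelial lines and of fibroblasts and mesenchymal cells. The first list had 0 of 5 exons changed in WT and 0 when adjusted over the list alone. Named exons were, for WT against mock, the 12 with the largest rise and the 12 with the largest fall among changed exons with a Bayes factor of at least 10, posterior intervals that did not overlap and a gene symbol. For each other RNA they were 4 in each direction, for direct comparisons 3 in each direction without the Bayes factor, for libraries that stood apart 4 each, and for lists up to 4 changed members. Events of PLEC, ERRFI1 and SNRPA1 were examined in addition. Some exons and genes that these rules would name, and the sequence and position of the element, are not reported here. Chosen after the data were seen were 5 further pairs of RNAs, sets of 2 libraries that stood apart, exons changed in all 5 RNAs, the WT minus loopN correlation, the covariances of read shares, the genes with the largest level differences, and the ratio of reads inside the PLEC exon to flanking reads, taken over mock and ranked among exons with at least 10000 reads.

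Alternatives were a difference of 0.2, a minimum of 50 reads, all events, libraries thinned to 2917294 reads over the exons shared by all, read numbers divided by 2, a Bayes factor of 20, the Bayes factor in place of Fisher's test, and, for PLEC, the share of reads. Later alternatives left out the structured library from the medians over comparisons, thinned the reads behind those medians, and lowered the minimum for PLEC to 1000 reads. Thinning and division by 2 changed the tested reads only, and the deposited inclusion levels were kept. The Fisher rule was tested on simulated data with 17955 exons at the depths of WT and mock. It recovered 7.46%, 35.8% and 77.3% of changes of 0.1, 0.2 and 0.4 in the share of reads, and called 0 of the unchanged exons. There the inclusion level was the share of reads itself, so cases where deposited levels depart from that share were not tested. Folding energies came from RNAfold 2.7.2, with mixed positions drawn at random or listed in full. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyfaidx 0.9.0.4, samtools 1.23.1 and matplotlib 3.10.9.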

Results

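RNA sequencing was used to ask how a structured RNA element, described by the submitters as bound by the U2 snRNP protein SNRPA1, changed exon use when it was introduced into MDA-LM2 cells, a highly metastatic human breast cancer line. There were 12 samples in 6 groups of 2: cells given transfection reagent without RNA (mock), and cells given the element (WT) or 1 of 4 altered forms. The structured pool carried paired changes meant to keep the stem. The loopN RNA had its loop randomised, the unstructured pool had 1 side of the stem altered, and the loopN_unstructured pool had both kinds of change. Each group was summarised in 1 pooled library of 2 samples, so no spread between replicates could be computed and each test compared pooled libraries rather than conditions. Reads that only the isoform with or only the isoform without an exon could explain numbered 6981593 in mock, 6070708 in WT, 3043618 in structured, 5673764 in loopN, 7737740 in unstructured and 7870745 in loopN_unstructured. Among exons with at least 20 such reads, the median 95% interval of the inclusion level was 0.09 wide in mock and WT and 0.12 wide in structured. The reads were amplified by PCR without molecular identifiers and are not independent molecules, so posterior intervals and tests of reads cover counting error only. Intervals of medians over genes or exons give the spread across these, and intervals of correlations treat exons as independent. None covers variation between replicates.

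The element matched hg38 at 1 place, in exon 31 of PLEC, the gene of the cytoskeletal linker plectin. The predicted folding energy was -15.9 kcal/mol for WT, and its mean over the listed sequences was -16.4 in the structured pool, -17.0 in loopN, -9.95 in the unstructured pool and -11.4 in the loopN_unstructured pool. On average 90.2% of the base pairs of WT were kept in the structured pool and 35.1% in the unstructured pool. One listed member of the structured pool kept 33.3% of them.

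The comparison of WT with mock asked which exons changed when the element itself was introduced. With 1 mock pool, a change that every RNA shares cannot be told apart from a trait of mock. PLEKHA1, which encodes a phosphoinositide-binding adaptor, included a 41-nt exon at a level of 0.95 (95% interval 0.87 to 0.99) in WT and 0.14 (0.04 to 0.27) in mock. GUK1, the guanylate kinase gene, included a 197-nt exon at 0.87 (0.72 to 0.96) and 0.11 (0.05 to 0.18). In the other direction, a 54-nt exon of NECAB3 fell from 0.90 (0.71 to 1.00) to 0.08 (0.02 to 0.20), and a 102-nt exon of C2CD5, whose product takes part in glucose transporter traffic, fell from 0.97 (0.90 to 1.00) to 0.24 (0.15 to 0.36). In all, 774 of 17955 exons changed, 412 to higher and 362 to lower inclusion in WT. The two-sided Fisher's exact test gave adjusted p = 9.48e-10 for PLEKHA1, 4.99e-09 for GUK1, 8.85e-07 for NECAB3 and 6.71e-14 for C2CD5. In hg38 these exons lie on chromosome 10 from 122428276 to 122428316 (PLEKHA1), chromosome 1 from 228141633 to 228141829 (GUK1), chromosome 20 from 33659497 to 33659550 (NECAB3) and chromosome 12 from 22458484 to 22458585 (C2CD5, where a gene is annotated on the opposite strand).

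The other exons with the largest rises reached several kinds of genes. Inclusion was 0.97 in WT and 0.33 in mock for LIMS2, a focal adhesion protein, with adjusted p = 0.0394 by Fisher's exact test. Its shares of tested reads lay closer, with 127 inclusion-only and 0 skipping-only reads in WT and 19 and 3 in mock. Inclusion was 0.91 and 0.30 for a 57-nt exon of the tyrosine phosphatase PTPN13. It was 0.84 and 0.28 for a 45-nt exon of HMMR, the hyaluronan-mediated motility receptor, and 0.94 and 0.34 for NLRC5, a transactivator of MHC class I genes. The pair was 0.94 and 0.36 for the lipid transporter SPNS2, 0.90 and 0.34 for HIBCH of valine breakdown, and 0.83 and 0.23 for the phosphoinositide-binding protein PLEKHA3. PDIK1L (0.85 and 0.22), BTBD2 (0.75 and 0.15) and the pseudogene transcript NSUN5P1 (0.95 and 0.36) completed this group. Some of these exons were far from mock in the altered RNAs too, such as NLRC5 (0.75 to 0.92) and HIBCH (0.74 to 0.95). Others lay nearer to mock there, such as BTBD2 (0.26 to 0.41).

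Among the largest falls, a 39-nt exon of UTRN, which encodes the dystrophin relative utrophin, was included at 0.23 in WT and 0.94 in mock. Inclusion in WT and mock was 0.28 and 0.92 for TRIP6, a focal adhesion protein, 0.15 and 0.76 for SDCCAG8 of the centrosome, and 0.30 and 0.92 for ABCD4, a lysosomal transporter. The protein kinase genes AKT2 (0.09 and 0.69) and PRKCD (0.28 and 0.88) lost inclusion of exons that lie wholly or partly in untranslated sequence. An 87-nt exon of EXOG, a mitochondrial nuclease, fell from 0.63 (0.43 to 0.82) to 0.03 (0.00 to 0.09). TOGARAM2 (0.26 and 0.91), CRYL1 (0.18 and 0.79) and PARP6 (0.31 and 0.89) were the remaining members. In the authors' deposited table, 1430 exons in WT had a Bayes factor of at least 10, 656 with higher and 774 with lower inclusion. This balance is opposite to that of the Fisher rule, and 653 exons met both rules. At equal depth 131 exons changed between WT and mock, and 117 did when each read number was divided by 2.

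The gene lists were fixed beforehand. For WT against mock, 14 of 158 exons in genes with splicing tied to the epithelial-mesenchymal transition changed, 7 in each direction, and 14 when adjusted over the list alone. They included a 145-nt exon of PLEKHA1 (0.97 and 0.22). It shares its start and its skipping reads (0 in WT, 22 in mock) with the 41-nt exon above, which is also counted. Others lay in the catenin gene CTNND1 (119 nt, 0.78 and 0.38) and the transcription factor gene TCF7L2 (102 nt, 0.96 and 0.69). Of 94 exons in genes of SR and SR-related proteins and their kinases, 7 changed, and 8 when adjusted over the list alone. Here RSRP1 (0.42 and 0.89) and SRRM1 (0.43 and 0.66) fell, and LUC7L (0.73 and 0.49) and SRSF11 (0.21 and 0.05) rose. In the list of hnRNPs and other splicing regulators 5 of 166 exons changed, and 6 when adjusted over the list alone. They included a 34-nt exon of PTBP3 (0.35 and 0.06), a 48-nt exon of RBM23 (0.29 and 0.50) and exons of RBFOX2 that rose (0.38 and 0.19, with a Bayes factor under 10 in the authors' deposited table) and fell (0.63 and 0.81). In the list of the U2 snRNP and branch point recognition 1 of 54 exons changed, a 67-nt exon of U2AF1 (0.72 and 0.51), and 1 when adjusted over the list alone.

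Genes of the cytoskeleton and adhesion had 8 of 230 exons changed in WT, 3 higher and 5 lower, and 9 when adjusted over the list alone. The 18-nt exons of the spectraplakin genes MACF1 and DST moved in opposite directions, to 0.60 from 0.15 and to 0.56 from 0.91. The DST exon had a Bayes factor under 10 in the authors' deposited table. Of 105 exons in cell cycle and DNA damage genes, 6 changed, and 7 when adjusted over the list alone. AURKA (0.98 and 0.59), CDK2 (0.70 and 0.40), BARD1 (0.91 and 0.69) and AURKB (0.23 and 0.06) rose. In the apoptosis list 3 of 89 exons changed, and 3 when adjusted over the list alone. An exon of BCL2L11 (0.31 and 0.60) fell, and an exon of CASP2 (0.12 and 0.02) rose. The deposited inclusion level of an exon of BCL2L12 was also lower in WT (0.56 and 0.74). Its tested reads went the other way, with 238 inclusion-only and 0 skipping-only reads in WT and 406 and 21 in mock. Of 87 exons in interferon and RNA sensing genes, 2 changed, in GBP3 (0.22 and 0.04) and LGALS3BP (0.18 and 0.03), and 2 when adjusted over the list alone. The median difference over exons of this list was 0.01 in WT, 0.01 in structured, 0.005 in loopN, 0.01 in unstructured and 0.02 in loopN_unstructured. These lay at percentiles of 99.93, 100, 99.94, 99.89 and 100 of random lists. Deposited levels are given in steps of 0.01, so these medians are near the rounding, and all share the 1 mock pool. The median log2 level of the list's genes was also above mock by 1.16 to 1.82, and an effect of this on inclusion levels was not tested. Of the other lists, cell cycle and DNA damage genes lay at percentile 0.06 in structured (-0.02), and epithelial markers at 1.615 in WT (-0.05, 5 exons) and 98.7 in unstructured (0.045, 4 exons); the rest lay in the middle 95% of random lists. Among fibroblast and mesenchymal markers 1 of 27 exons changed, in COL6A3 (0.97 and 0.81), and 1 when adjusted over the list alone. Among epithelial markers 0 of 5 exons changed, and 0 when adjusted over the list alone.

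The 4 altered RNAs were each compared with the same mock pool. With the structured pool, inclusion rose in ADGRL2 (0.90 from 0.25), an adhesion receptor gene, VPS37A (0.76 from 0.20), a gene of endosomal sorting, DDIAS (0.73 from 0.18) and ME3 (0.83 from 0.32). It fell in METTL8 (0.11 from 0.78), ZNF26 (0.32 from 0.87), EXOG (0.08 from 0.63) and PRKCD (0.34 from 0.88). With loopN it rose in EBPL (0.85 from 0.14), SIPA1L1 (0.83 from 0.18), EYA3 (0.87 from 0.24) and RAP1GDS1 (0.63 from 0.02), and fell in TMEM129 (0.13 from 0.84), METTL26 (0.32 from 0.95), TRIP6 (0.30 from 0.92) and LZTR1 (0.16 from 0.78). With the unstructured pool it rose in the collagen gene COL13A1 (0.83 from 0.13), VPS37A (0.87 from 0.20), RDH13 (0.94 from 0.28) and the kinase gene MAP3K8 (0.98 from 0.38). It fell in LARP1B (0.02 from 0.92), SNED1 (0.09 from 0.95), SAMD10 (0.09 from 0.91) and PACRGL (0.11 from 0.85). For RDH13 the shares of tested reads lay closer, with 229 inclusion-only and 0 skipping-only reads in unstructured and 65 and 7 in mock. With the loopN_unstructured pool inclusion rose in RPF2 (0.90 from 0.15), ARMCX5-GPRASP2 (0.92 from 0.24), ZNF85 (0.81 from 0.16) and PTPN13 (0.93 from 0.30). It fell in SLC38A9 (0.17 from 0.92), EXOG (0.02 from 0.63) and SDCCAG8 (0.20 from 0.76). In the other RNAs ARMCX5-GPRASP2 also lay far from mock, at 0.67 to 0.88, whereas RPF2 lay at 0.05 to 0.21.

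Against mock, 235 of 14795 exons changed with the structured pool (112 higher), 862 of 17367 with loopN (413 higher), 756 of 18381 with the unstructured pool (369 higher) and 579 of 18653 with the loopN_unstructured pool (320 higher). In the authors' deposited table the exons with a Bayes factor of at least 10 numbered 706, 1434, 1350 and 1098 in the same order. Of these, 317, 708, 663 and 535 were higher. In loopN_unstructured 563 were lower, so the balance there is opposite to that of the Fisher rule. At equal depth the Fisher counts were 66, 185, 73 and 42, and with read numbers divided by 2 they were 1, 138, 86 and 23.

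The direct comparisons between RNAs asked whether the stem or the loop mattered for exon use. Between WT and the unstructured pool, exons of the scaffold gene MAGI3 (0.95 in WT, 0.14 in unstructured), CAPRIN2 (0.86, 0.05) and DDX60L (0.90, 0.15) were higher in WT. Exons of the lncRNA IRX2-DT (0.03, 0.96), the nuclear receptor coactivator NCOA1 (0.13, 0.88) and C2CD5 (0.24, 0.96) were lower in WT. Between WT and loopN, ZNF619 (0.92 in WT, 0.24 in loopN), GUK1 (0.87, 0.20) and ZNF75A (0.95, 0.29) were higher in WT, and NECAB3 (0.08, 0.95), NCOA1 (0.13, 0.95) and the mitochondrial carrier SLC25A16 (0.20, 0.92) were lower. Between WT and the structured pool, which was built to keep the stem and loop, the mitochondrial carrier SLC25A23 (0.95 in WT, 0.29 in structured), PLEKHA3 (0.83, 0.21) and the ciliary gene IFT122 (0.89, 0.34) were higher in WT. NCOA1 (0.13, 0.92), B3GALNT2 (0.08, 0.82) and PLEKHM2 (0.18, 0.86) were lower in WT. The changed exons numbered 990 of 18037 between WT and unstructured, 1019 of 17075 between WT and loopN and 441 of 14733 between WT and structured. At equal depth they numbered 186, 333 and 220 in the same order, so the low count for structured, the library with the fewest reads, did not hold.

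The structured and unstructured pools differed in 411 of 14827 exons. Among them NPHP4 (0.93 in structured, 0.21 in unstructured), VPS53 (0.94, 0.28) and the activin receptor gene ACVR1B (0.83, 0.20) were higher in structured, and FAM219B (0.14, 0.81), METTL8 (0.11, 0.74) and ZNF654 (0.31, 0.94) were lower. The loopN and loopN_unstructured libraries differed in 864 of 17630 exons. LRRN1 (0.94 in loopN, 0.16 in loopN_unstructured), COQ7 of ubiquinone synthesis (0.91, 0.19) and SAMD12 (0.90, 0.20) were higher in loopN. ZNF561 (0.15, 0.87), ALKBH6 (0.19, 0.88) and ZNF75A (0.29, 0.96) were lower. For ALKBH6 the shares of tested reads lay closer, with 19 inclusion-only and 4 skipping-only reads in loopN and 66 and 0 in loopN_unstructured. Over all 10 pairs of RNAs, of which 5 were added after the data were seen, the median number of changed exons was 828, against 756 over the 5 comparisons with mock. At equal depth these medians were 183.5 and 73. With read numbers divided by 2, the 5 direct comparisons set beforehand gave 210, 237, 19, 25 and 186 exons, in the order in which they are given here.

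**Figure D1:**
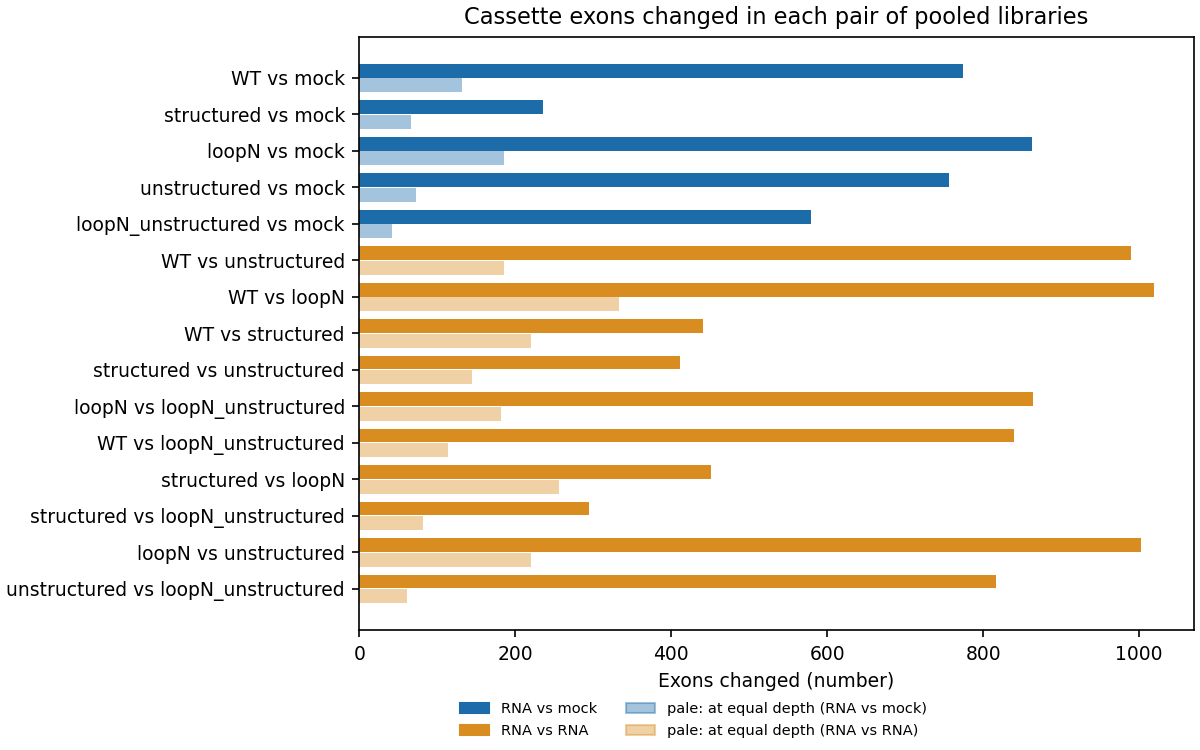
Number of cassette exons changed in each of the 15 pairs of the 6 pooled libraries. Comparisons with mock are in blue and comparisons of RNAs in orange. Pale bars give the number with the tested reads thinned to equal depth and the deposited levels kept. Counts lay between 235 and 862 against mock and between 294 and 1019 between RNAs.

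To hold the WT library against the others without replicates, exons were counted in which 1 library differed from each of the other 5 in the same direction. In WT, TADA2A, a gene of histone acetyltransferase complexes (0.45 in WT, 0.86 to 0.98 elsewhere), SKA3 of the kinetochore (0.41, 0.81 to 0.97), the nucleotidase gene NT5C2 (0.33, 0.73 to 0.96) and TMX3 (0.58, 0.93 to 0.98) stood apart with lower inclusion. In mock, EXOG (0.63, 0.02 to 0.12) and RSRP1 (0.89, 0.40 to 0.61) stood apart with higher, and VRK3 (0.55, 0.91 to 0.96) and CHURC1-FNTB (0.30, 0.64 to 0.78) with lower inclusion. In the structured library ZNF26, SLC25A26, SLC25A23 and METTL8 were lower, and in loopN ZNF561 and CCDC85C were lower and PAQR3 and RALGPS2 higher. In the unstructured library AHI1, BLOC1S6 and NPRL3 were lower and FAM219B higher, and in loopN_unstructured INPP5F, SGCE and MTMR14 were lower and SPATS2 higher. Of 14082 exons, 132 set WT apart, 174 loopN, 95 structured, 79 unstructured, 45 mock and 35 loopN_unstructured, each at unadjusted p under 0.05 in all 5 tests. At equal depth the counts were 50, 74, 43, 32, 18 and 12.

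**Figure D2:**
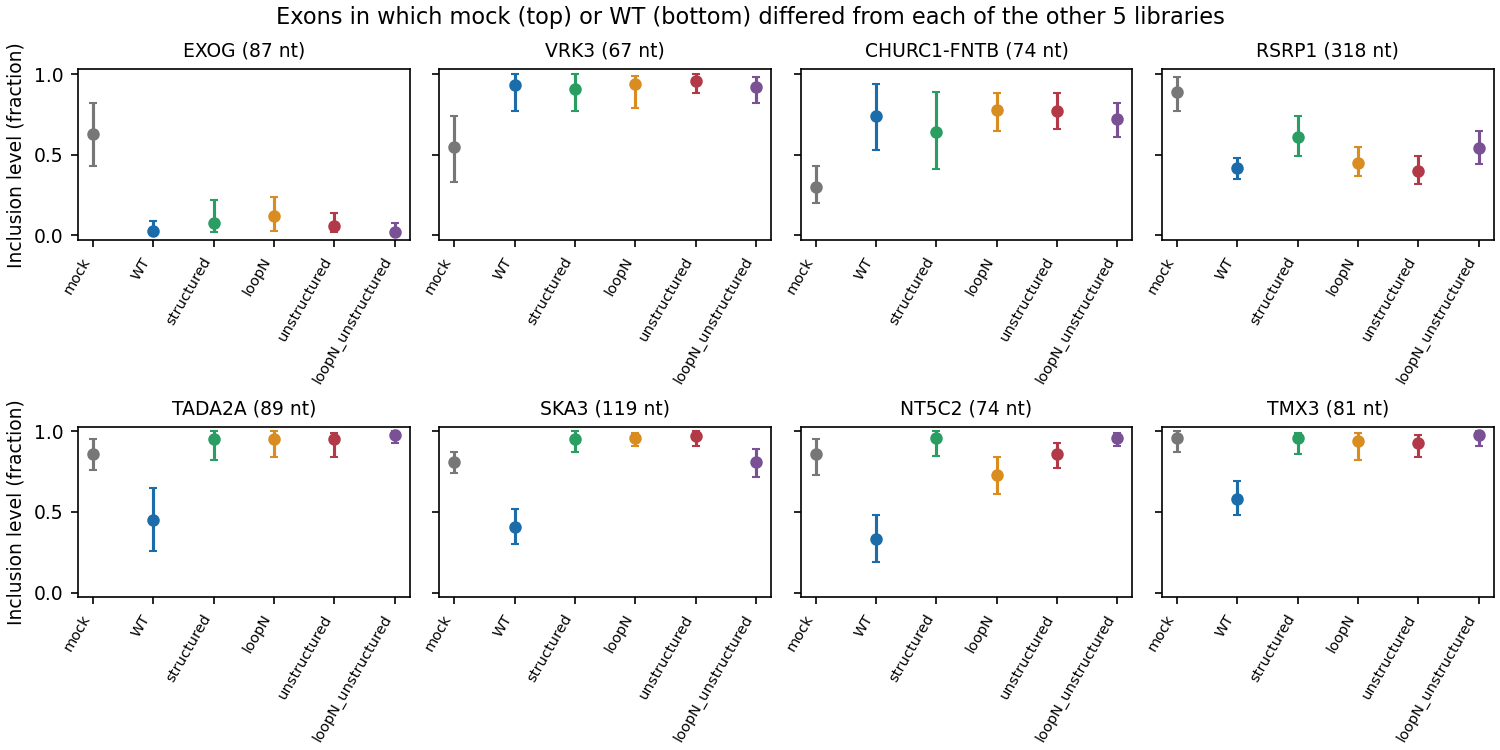
Inclusion level (fraction, points) with its 95% posterior interval (bars) in the 6 pooled libraries for 4 exons that set mock apart (top) and 4 that set WT apart (bottom). In EXOG mock lies at 0.63 and every RNA at or under 0.12, and in TMX3 WT lies at 0.58 and the other libraries at or above 0.93.

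WT and the structured pool stood apart together from the other 4 libraries in 8 exons, a count added after the data were seen. Inclusion was lower in both in PRKCD (0.28 and 0.34, against 0.56 to 0.88 elsewhere), ZNF654 (0.37 and 0.31, against 0.70 to 0.94), TANK (0.23 and 0.22, against 0.34 to 0.49), KIAA1191 and VTA1. It was higher in both in the tumour suppressor gene VHL (0.46 and 0.45, against 0.23 to 0.28), MTX2 (0.43 and 0.35, against 0.15 to 0.19) and ZNF384. Other pairs of libraries stood apart together in 3 to 16 exons. Across 14082 exons, which are not independent replicates, the WT minus mock difference had r = 0.0025 (rho = 0.0178; r = -0.0038 with all events) with the structured minus unstructured difference and r = 0.0052 (rho = 0.00365) with the loopN minus loopN_unstructured difference. Over the 45 pairs of differences without a shared library, the largest absolute r was 0.0881. With mock shared, r between WT and the other RNAs was 0.401 for structured, 0.352 for loopN, 0.40 for unstructured and 0.415 for loopN_unstructured. Computed on the shares of reads it was 0.325, 0.306, 0.349 and 0.394, where simulated reads with 1 level per exon in all libraries gave 0.392, 0.452, 0.486 and 0.493. The covariance of the read shares, added after the data were seen, was 0.00125, 0.00133, 0.00132 and 0.00135, where simulated reads gave 0.000336, 0.000334, 0.000336 and 0.000333.

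In 13 exons inclusion changed in the same direction in all 5 RNAs against the shared mock, a count added after the data were seen. Those in which it rose included exons of SPAG9 (0.08 in mock, 0.22 to 0.27 with RNA), the mitochondrial glycine carrier gene SLC25A38 (0.69, 0.92 to 0.98) and FBXW11 (0.69, 0.82 to 0.90). Those in which it fell included exons of EXOG, the Hippo pathway gene SAV1 (0.13, 0.00 to 0.03), MAP4K4 (0.26, 0.06 to 0.16), PHYKPL (0.89, 0.49 to 0.62), UMAD1 (0.16, 0.04 to 0.05) and the nuclear envelope gene SUN1 (0.93, 0.58 to 0.76). Another 2 that fell were overlapping exons of ZNG1E, a member of a family of near-identical copies whose reads can be placed in more than 1 copy.

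PLEC, which holds the element, and ERRFI1, a feedback inhibitor of EGF receptor signalling, were examined because the study concerns them. The PLEC exon was included at 1.00 in all 6 libraries, with 29 to 84 reads that skipped it. Reads inside it relative to reads of the flanking exons were higher than in mock by a factor of 2.64 in structured, 2.38 in loopN, 2.02 in unstructured and 1.40 in loopN_unstructured, and the factor was 0.977 in WT. Among the 37 exons with at least 10000 reads this factor ranked 1 in each of the 4 altered RNAs and 16 in WT. With a minimum of 1000 reads and 969 exons, chosen after the data were seen, it ranked 1 in structured, loopN and unstructured, 27 in loopN_unstructured and 480 in WT. As a share of all compatible reads, reads of the flanking PLEC exons were 1.11 times mock in WT, 0.960 in structured, 1.05 in loopN, 1.26 in unstructured and 1.2 in loopN_unstructured. Position inside the exon was not analysed here.

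**Figure D3:**
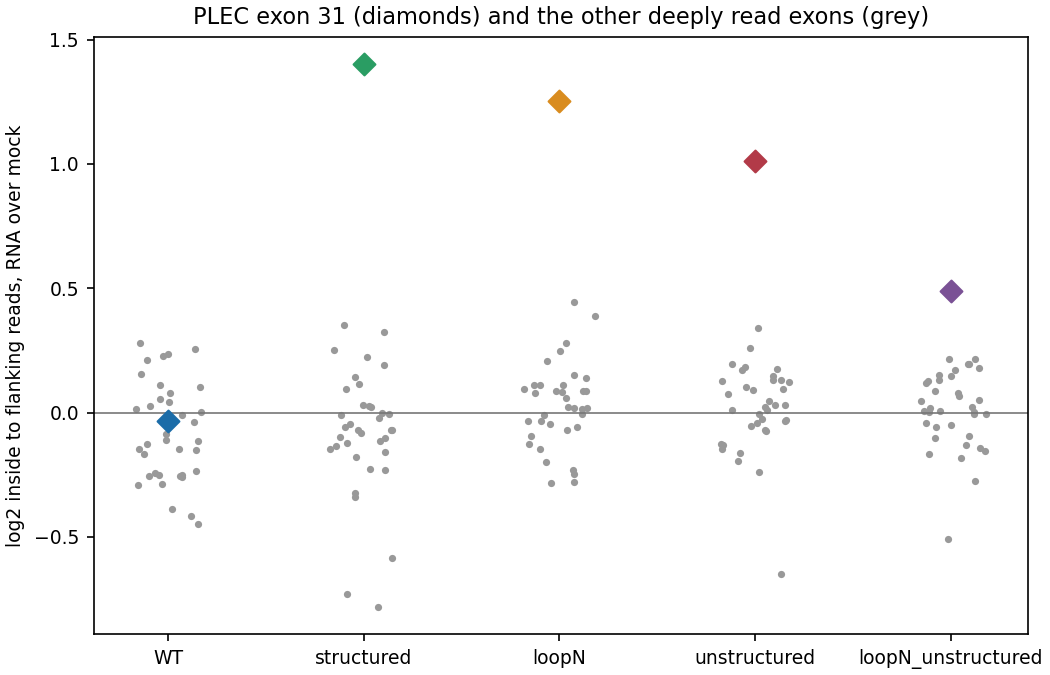
Log2 ratio of reads inside an exon to reads of its flanking exons, each RNA over mock, for PLEC exon 31 (diamonds) and the other exons with at least 10000 reads (grey points). PLEC lies at 1.40 in structured and at -0.03 in WT, and the highest other exon in structured lies at 0.35.

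The 77-nt exon of ERRFI1, on chromosome 1 from 8015308 to 8015384, was included at 0.49 (0.44 to 0.56) in mock, 0.38 (0.33 to 0.43) in WT, 0.22 (0.18 to 0.27) in structured, 0.47 in loopN, 0.57 in unstructured and 0.43 in loopN_unstructured. In the authors' deposited table its Bayes factor against mock was 2.85 in WT and 1e12 in structured. The Fisher rule did not call this exon in any RNA, with 0 to 14 reads of the skipping isoform per library. Inclusion levels of the overlapping 93-nt exon were 0.07 to 0.16. No exon of SNRPA1 itself changed by the Fisher rule. Its 80-nt exon was included at 0.96 to 0.99, and its 101-nt untranslated exon at 0.18 in WT and 0.05 in mock, with a Bayes factor of 41392 in the authors' deposited table and too few reads for the Fisher test. Its 47-nt exon was included at 0.71 (0.53 to 0.91) in structured and 0.39 (0.31 to 0.50) in mock, with a Bayes factor of 26.7 in the authors' deposited table and 0 skipping reads in every library.

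Gene levels, taken from the reads of each gene's most covered exon event, were set beside mock in 8395 genes, with no test because each condition was 1 library. Antiviral genes were higher with every RNA: IFIT1, which binds viral RNA, was higher on the log2 scale by 3.12 in WT, 3.49 in structured, 2.91 in loopN, 3.67 in unstructured and 3.45 in loopN_unstructured. OASL was higher by 3.58, 3.68, 3.29, 4.11 and 3.98 in the same order, and the RNA sensor IFIH1 by 2.72, 3.42, 2.54, 3.24 and 2.85. The median log2 ratio of the 48 measured genes of the interferon and RNA sensing list was 1.39 (95% interval 0.79 to 2.03) in WT, 1.61 in structured, 1.16 in loopN, 1.82 in unstructured and 1.68 in loopN_unstructured, above all 10000 random lists of like level in each RNA. Of the 48 genes, 47 were above mock in loopN and all were above it in the other RNAs. The level minimum was a mean over 6 libraries, 5 of them with RNA, so genes low only in mock could pass it. The genes named here were picked after their values were seen. Between RNAs the largest median over genes of the difference was -0.63 (-0.77 to -0.48), loopN minus unstructured.

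**Figure D4:**
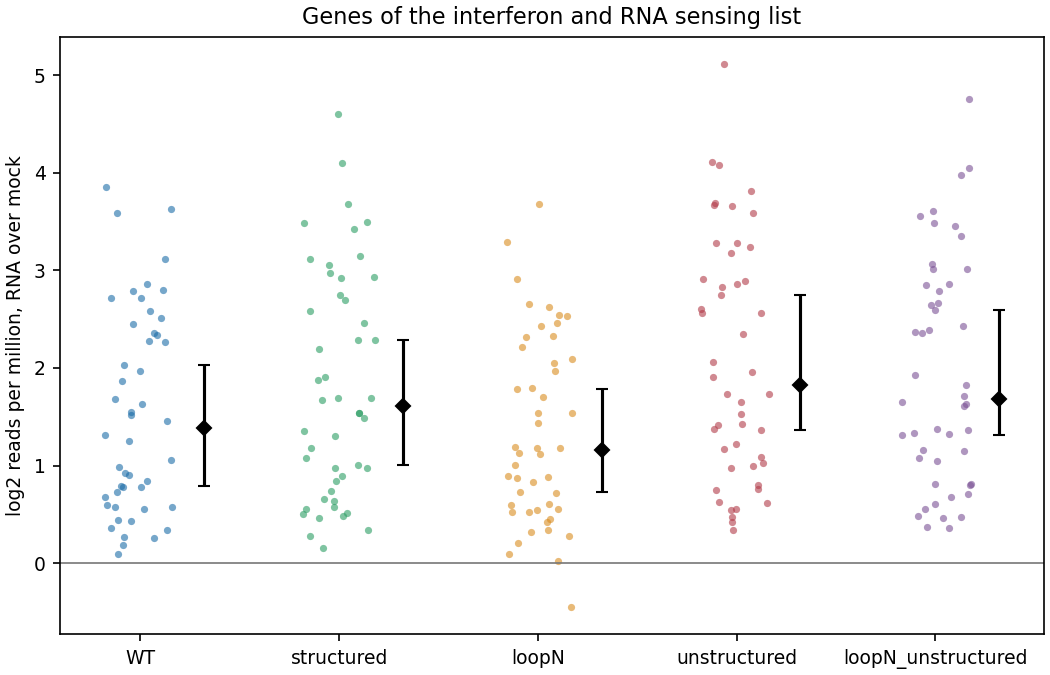
Log2 ratio of gene levels (share of all compatible reads), each RNA over mock, for the 48 measured genes of the interferon and RNA sensing list (coloured points), with their median and its 95% interval (black). The medians lie between 1.16 in loopN and 1.82 in unstructured.

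Most cell cycle and DNA damage genes were lower than mock with every RNA, and 8 of the 33 measured genes in WT, 6 in structured, 7 in loopN, 6 in unstructured and 6 in loopN_unstructured were above it. The median log2 ratio was -0.31 in WT, -0.27 in structured, -0.31 in loopN, -0.53 in unstructured and -0.43 in loopN_unstructured, at a percentile of 0.175 of random lists in structured and 0 in the other RNAs. Among them CDK1, the mitotic kinase gene, had log2 ratios of -0.78, -0.83, -0.80, -0.91 and -0.72 in that order. In the same order, genes of hnRNPs and splicing regulators had medians of -0.13, -0.08, -0.19, -0.26 and -0.22, at percentiles of 1.19, 19.2, 0.13, 0.18 and 0.20 of random lists, and genes of SR proteins -0.13, -0.02, -0.16, -0.25 and -0.22, at percentiles of 2.49, 46.2, 1.13, 0.92 and 0.71. The U2 snRNP list had medians of -0.09, -0.25, 0.00, -0.14 and -0.12, at percentiles of 11.8, 1.09, 69.5, 18.2 and 18, and the epithelial-mesenchymal list 0.06, 0.16, 0.03, 0.20 and 0.07, at percentiles of 84.0, 99.3, 86.3, 99.92 and 93.9. Medians were -0.01 in WT and between -0.09 and -0.03 in the other RNAs for the cytoskeleton list, and -0.07 in WT and between 0.00 and 0.12 in the others for the apoptosis list. Of the marker lists, 5 epithelial genes had a median of -0.06 in WT and between 0.14 and 0.49 in the other RNAs, and 8 fibroblast and mesenchymal genes 0.29 in WT and between -0.08 and 0.30 in the others. With all events the medians in WT were 0.036 for the cytoskeleton list and 0.17 for the epithelial genes.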

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

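The tests of PLEC messenger RNA, of transfected RNA in WT, of transfected RNA with the minimum of 1000 reads and of a WT library without RNA were chosen after the result was seen, as were those of counting noise in the comparisons other than WT with mock, of PCR copies, of a response that needs stem and loop, of a shift of all genes, of low depth in mock and of transfected RNA whatever its structure. The other tests in this part were set before their own values were seen, that of the PLEC rank once the higher reads in that exon were known.

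Reads inside PLEC exon 31, relative to flanking reads, were higher than in mock by 2.64 in structured, 2.38 in loopN, 2.02 in unstructured and 1.40 in loopN_unstructured, and WT differed from each by a test of the reads. More PLEC messenger RNA as the whole source is argued against in structured, loopN and unstructured, since it would raise flanking reads alike, and these were 0.960, 1.05 and 1.26 times mock; a part in unstructured and loopN_unstructured, where they were 1.2 times mock or more, stays open. Reads of the transfected RNA, which shares sequence with this exon alone, are a candidate source: the exon ranked 1 among exons with at least 10000 reads in all 4 RNAs and 1 among 969 with at least 1000 in structured, loopN and unstructured, but 2.68% of those exons lay above it in loopN_unstructured, where the source stays open. In WT the log2 ratio was -0.0341, which argues against such reads there. A WT library from cells without RNA stays open: the interferon list lay at 1.39 over mock, but this cannot be told apart from a peculiarity of the mock pool. Why the WT RNA left no such trace was not tested.

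As many exons differed between RNAs as between an RNA and mock. Counting noise of independent reads gave 0 exons at adjusted p under 0.05 in any of 20 draws for WT and mock, against 1402 observed, and at most 1 in the other 14 comparisons, against at least 392 observed. The drawn reads follow the model that Fisher's test assumes, so such low counts were fixed in advance and add nothing beyond the adjusted p. At equal depth 9 of the 10 comparisons of RNAs reached the median of those with mock. This argues against unequal numbers of tested reads as the whole source. The deposited levels in the rule were not thinned, so depth behind those levels stays open. PCR copies counted as separate reads stay open, because the number of copies is not known: with read numbers divided by 2 the changed exons numbered from 1, for structured and mock, to 252, for loopN and unstructured. For a response to the element that needs its paired stem and its loop, the pairs of libraries that stood apart decide nothing. In 6 of the 14 other pairs at least as many exons stood apart as in WT and structured. Structured had the fewest test reads (3043618), which limits its pairs, and these counts were not thinned. Such a response would not separate loopN, with its loop randomised, from unstructured, with its stem altered. Yet 1002 exons differed between them (220 at equal depth), which argues against it as the whole source. Variation between wells or libraries stays open, because each condition is 1 pool and its spread cannot be measured, and a response to each RNA's own sequence stays open as well.

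Interferon and RNA sensing genes took a larger share of reads in all 5 RNAs than in mock. A shift of all genes of like level is argued against, since the list lay at percentile 100 of random lists in every RNA. Low depth in mock as the whole source is argued against by the 36 genes with at least 100 reads in mock, whose lowest median over RNAs was 0.951, with intervals that began at 0.595 or higher. The test set beforehand, on the 43 genes with at least 1000 reads over all libraries, gave 1.13 and decides nothing, because the rise itself brings genes past that limit. A response to transfected RNA whatever its structure may account for it: the median over genes of the difference was at most 0.63 between RNAs and at least 1.16 between an RNA and mock. It cannot be told apart from a peculiarity of the mock pool, which is 1 library.

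Some exons moved in opposite directions in WT and another RNA against mock, and nearly all of these also differed in the direct test. Exons called on opposite sides of mock can hardly fail that test, so it adds no support. Those past the direct test numbered 4 of 4 for structured, 13 of 13 for loopN, 6 of 6 for unstructured and 9 of 10 for loopN_unstructured. The number expected from independent lists was not computed for opposite directions, so no conclusion is drawn from these counts.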

How the results depend on the processing

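The alternatives that thin the reads behind the medians over comparisons, leave out the structured library and lower the PLEC minimum to 1000 reads were chosen after the data were seen. With all events 3 values whose intervals include 0 changed sign. The correlation of WT minus mock with structured minus unstructured was -0.0038. The median log2 level in WT was 0.036 for the cytoskeleton list and 0.17 for the epithelial markers. With the Bayes factor in place of Fisher's test, exons lower than mock came to outnumber higher ones in WT (774 and 656) and loopN_unstructured (563 and 535). No other result with a sign reversed it under any alternative run. No paired analysis was possible because the summaries hold no separate columns for replicates 1 and 2, so neither a replicate block nor leaving out a replicate was run. Counts depended on depth and thresholds, by construction for stricter rules and fewer reads. Depth limits what is seen: at the depths of WT and mock 7.46% of simulated changes of 0.1 were recovered. With all events (53 values), a Bayes factor of 20 (5), the share of reads for PLEC (6) and the medians without the structured library (765 against mock, 927 between RNAs), each value stayed within 1.5 times its count or within its interval. So did 30 values at a minimum of 50 reads, 5 at a difference of 0.2, 6 at equal depth and 3 of the PLEC ranks at 1000 reads.

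For WT, structured, loopN, unstructured and loopN_unstructured against mock, a difference of 0.2 gave 426, 140, 446, 399 and 313 exons. A minimum of 50 reads gave 490, 120, 567, 490 and 352, equal depth 131, 66, 185, 73 and 42, read numbers divided by 2 gave 117, 1, 138, 86 and 23, and the Bayes factor in place of Fisher's test 1430, 706, 1434, 1350 and 1098. With 50 reads the Bayes factor counts were 911, 391, 915, 875 and 712. For WT and unstructured, WT and loopN, WT and structured, structured and unstructured, and loopN and loopN_unstructured, a difference of 0.2 gave 561, 569, 248, 249 and 446, equal depth 186, 333, 220, 144 and 181, and divided read numbers 210, 237, 19, 25 and 186. A minimum of 50 reads gave 615, 656, 241 and 195 in the first 4 of these.

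Exons that set mock, WT, structured, loopN, unstructured and loopN_unstructured apart numbered 15, 44, 41, 56, 30 and 7 at a difference of 0.2, 27, 73, 38, 85, 35 and 22 at 50 reads, and 18, 50, 43, 74, 32 and 12 at equal depth. At equal depth the medians were 73 against mock and 183.5 between RNAs. With 50 reads the correlation of WT minus mock was 0.0295 with loopN minus loopN_unstructured, 0.38 with loopN minus mock and 0.430 with loopN_unstructured minus mock; the cause was not tested. With 1000 reads PLEC ranked 27 in loopN_unstructured and 480 in WT, among 969 exons in place of 37.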

Other observations

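The counts of list members in the altered RNAs follow rules set beforehand; the WT minus loopN correlation, the test of the loop sequence as the source of most of a set and the choice of level genes named here came after the data were seen.

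In the list of hnRNPs and splicing regulators, 1 of 148 exons changed with structured, 10 of 164 with loopN, 5 of 167 with unstructured and 4 of 171 with loopN_unstructured, and 1, 10, 5 and 4 when adjusted over the list alone. With loopN they included exons of TIAL1 (0.41 from 0.04), FXR2 (0.36 from 0.07), MBNL1 (0.74 from 0.98) and CELF1 (0.35 from 0.55). A 54-nt exon of MBNL2 rose to 0.25 in unstructured and 0.30 in loopN_unstructured, from 0.06. The 318-nt exon of RSRP1, in the list of SR proteins, fell from 0.89 to 0.45 in loopN, 0.40 in unstructured and 0.54 in loopN_unstructured. In the U2 snRNP list 0 of 51, 1 of 55, 3 of 53 and 1 of 55 exons changed with structured, loopN, unstructured and loopN_unstructured, and 0, 1, 3 and 1 when adjusted over the list alone. With the unstructured pool, exons of U2AF1L4 fell to 0.38 from 0.66 and to 0.20 from 0.47, and a 231-nt exon of RBM10 rose to 0.56 from 0.36.

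Genes tied to the epithelial-mesenchymal transition had 8 of 140 exons changed with structured, 12 of 155 with loopN, 10 of 158 with unstructured and 8 of 158 with loopN_unstructured, and 9, 14, 12 and 11 when adjusted over the list alone. In structured, overlapping 201-nt and 204-nt forms of a MAGI1 exon, with the same tested reads, were both counted. A 45-nt exon of EXOC1 fell from 0.69 in mock to 0.14 in loopN and 0.33 in loopN_unstructured. In ZEB1, a repressor of epithelial genes, a 60-nt exon fell from 0.81 to 0.52 in loopN. Among cytoskeletal genes, an exon of ANK3 of 2583 nt was included at 0.65 in loopN and 0.07 in mock, and a 90-nt exon of MYO9B at 0.71 and 0.14. Some genes outside the interferon list also had higher levels: ZBTB32 by 4.47 in WT and 4.99 in loopN_unstructured on the log2 scale, SOD2 by 2.44 and 3.01, and IL6 by 1.97 and 2.41. In all, 76 genes were higher by at least 1 on this scale in all 5 RNAs and 0 were lower by as much. The level minimum was a mean over 6 libraries, 5 of them with RNA. It admits genes low in mock more readily than genes high only in mock, and both counts share the 1 mock pool. No conclusion is drawn from the difference between these counts.

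Of the exons with lower inclusion in WT, 14.9% held the loop sequence of the element, where 12.9% is expected from exons of like length. This share lay at percentile 88.3 of random draws, and the share among exons with higher inclusion in WT, 10.7% where 13.2% is expected, at percentile 5.56. The loop sequence inside the exon as the source of most of the lower set is argued against by the 14.9% that held it. A part stays open: the test set beforehand took a share within the middle 95% of draws as evidence against any part, but draws up to 16.3% leave room for a small excess. Of the 45 exons that set mock apart, 0% lay in genes of the interferon list, which held 0.597% of all exons tested in the 6 libraries; this argues against interferon genes as the source of most of that set.

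The correlation of WT minus loopN with structured minus unstructured was 0.0496. Its interval of 0.0331 to 0.0661 treats exons as independent replicates, which they are not. The value lies under 0.0881, the largest absolute r over the 45 pairs of differences without a shared library.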
